A study of Mus musculus with 6 samples.

How the data were processed

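RNA was taken from the microdissected second heart field region of mouse embryos at embryonic day 9.5, in 2 groups: controls with Mef2c-Cre and Hoxb1 gain-of-function (GoF) samples with Mef2c-Cre. Per the labels' protocols, cDNA was made from 2 ng of total RNA with random and poly-T primers, amplified by single primer isothermal amplification, and sonicated, and 100 ng of it went into each sequencing library. Amplification of this kind can favour some transcripts by their composition. The labels do not say how the amplified samples were batched. Random priming keeps ribosomal and mitochondrial RNA in the libraries.

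The submitters' processing notes name bcl2fastq 2.17.1.14, STAR 2.5.2, HTSeq, R and DESeq2, and the build mm10. The annotation, the strand setting and the filters are not given in the sources used here. Without a strand setting, reads of overlapping genes and antisense partners cannot be told apart. The authors' deposited table holds 16832 genes, each with a signal per library, the mean of these signals, a log2 fold change, a test score, a p-value and an adjusted p-value. Per the file headers the library values are normalized, and within each column of deposited signal every value was a whole multiple of 1 step (100% of values within 0.001 of a whole number). The signal is thus a read count divided by 1 factor per library, called normalized count here, and the whole reads could be recovered. DESeq2 size factors computed from these reads differed from the deposited factors by a relative 6.7e-16 at most. The deposited log2 fold change, score and p-value are the authors' comparison and were copied. The names of 13 genes in it were dates, as a spreadsheet makes them from some gene symbols, and were kept as they stood. The lowest mean normalized count in the table was 6.1, so genes below that were not analysed here.

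The table has columns for 2 controls and 3 GoF samples, and control replicate 1 was not analysed here. The design written before the data were examined assumed all 6 samples and gave 1 test for raw counts and another for normalized values. As the table holds normalized values, the second was used. Log2(normalized count + 1) was fitted with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend and robust), without covariates, for genes with a mean of at least 10. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called. The recovered reads were also tested with DESeq2 1.42.0, as planned, and with the quasi-likelihood test of edgeR 4.0.16, added after the data were seen. DESeq2 called 2212 genes higher and 2241 lower, and edgeR 2090 and 1708. With 2 controls, each test rests on few degrees of freedom. The depth was 34260116 to 44384354 reads per library. Intervals from counting were not used, since reads amplified without molecular identifiers are not independent molecules.

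The fits were tested on simulated counts for the real genes, with 2 libraries against 3 and a dispersion of 0.033. The simulated libraries were independent and every gene had this dispersion, so the error rates need not hold for the real libraries. The limma test recovered 53% of genes changed 2-fold and 97% of those changed 4-fold, with 9 of the unchanged genes called among 16788 tested. The edgeR test recovered 55% and 97%, with 7 unchanged genes called among 16805. With a simulated GC trend between the groups, limma called 727 unchanged genes among 16772, and 8 among 16243 once the trend was removed, with 61% and 94% of the changed genes recovered.

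Gene lists for 32 pathways, cell types and complexes were written before the data were examined. Each was tested with camera at its preset correlation of 0.01 on the same log2 values, adjusted over the 32 lists, and again with an estimated correlation, with which no list passed. The lists cover Hox genes and cofactors, both parts of the second heart field, branchiomeric muscle, sarcomere, calcium handling, cardiac transcription factors, 5 signalling pathways, p53 targets, apoptosis, cell cycle, hypoxia and glycolysis, stress genes, mitochondria, matrix, cell types and sex-linked genes. The named genes follow a rule of the same time. They are Hoxb1, the 10 highest and 10 lowest fold changes among called genes with a mean of at least 50 and no overlap between the groups, up to 4 called members of each list with the lowest adjusted p (or 2 of the most expressed where none passed), and the Hox cluster genes. Predicted gene models, of which 470 met the limits, were not named by the rule. Other genes are named with a remark that they were chosen later.

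GC content was that of the longest GENCODE M21 transcript (build GRCm38, the same as mm10), matched by symbol for 16302 of the 16832 genes (96.9%), and coordinates come from the same annotation. To remove the GC trend, a lowess curve (span 0.3) of each library's deviation from the gene mean on GC content was subtracted. This step was added after the data were seen. It also removes any true change that follows GC content. Other alternatives were quantile normalization, no filter or a mean of at least 50, array weights, pseudocounts of 0.5 and 5, a block for the replicate number, leaving out each library in turn, and a limit on the fold change. Libraries of the same group were compared in pairs by the median over 13281 genes of the squared difference over its counting variance. This value, here the variance ratio, is 1 for repeat sequencing of the same library. It was 13.5 between the controls and 3.9, 3.86 and 12.5 between GoF replicates 1 and 2, 1 and 3, and 2 and 3. No library was thus a resequencing of another, while a second library of the same RNA is not excluded by these ratios. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for tables and plots.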

Results

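Gene expression was measured by RNA sequencing in the second heart field region, microdissected from mouse embryos at embryonic day 9.5. The second heart field is a pool of progenitor cells that adds myocardium to both poles of the growing heart tube. Hoxb1 is a homeobox transcription factor whose expression marks its posterior part. The gain-of-function (GoF) samples carried a Hoxb1 GoF allele together with Mef2c-Cre, which drives Cre recombinase in second heart field cells, and the control samples carried Mef2c-Cre. The series lists 3 samples per group. The deposited values cover 2 controls, replicates 2 and 3, and 3 GoF samples, replicates 1 to 3, and control replicate 1 was not analysed here. The labels do not say whether replicates came from separate embryos, so the p-values measure only the spread between these libraries. The normalized read counts gave back 44384354 and 34342568 reads for control replicates 2 and 3, and 34260116, 44191917 and 42853609 reads for GoF replicates 1, 2 and 3. Mitochondrial genes took 50.7% and 44.4% of the control reads and 36.7%, 37.4% and 35.7% of the GoF reads, most of it mitochondrial ribosomal RNA.

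The comparison of GoF with control asks which genes differ when Hoxb1 is raised in this region. It cannot tell responses to Hoxb1 from other differences between the groups. Hoxb1 (mm10 chromosome 11, 96365752 to 96368256) was at 751.6 and 610.2 normalized counts in the controls and at 1021.8 ± 19.1 in the GoF libraries (SD, n = 3), a 1.51-fold rise (log2 fold change 0.59, SE 0.12, limma adjusted p = 0.0147). Glycolytic enzyme genes rose: Pfkl, a phosphofructokinase subunit, was 3.73-fold higher, Gapdh 2.62-fold and Ldha, lactate dehydrogenase A, 2.31-fold. Bmp4, a secreted growth factor of the heart-forming region, rose 2.25-fold, the retinoic acid binding protein gene Crabp2 rose 2.53-fold, and Osr1, a transcription factor of the posterior second heart field, rose 4.26-fold. Fgf10, the growth factor that marks the anterior second heart field, fell to 0.53 of the control level, Ebf3 to 0.52, and Mki67, a proliferation marker, to 0.62. Other genes of these kinds went both ways. Of 17 anterior second heart field genes 3 rose and 3 fell, and of 32 cell cycle genes 7 rose and 2 fell. The Hoxb1 call was lost without GoF replicate 1 (adjusted p = 0.0601) and with a trend on GC content removed from the values (log2 fold change 0.26, SE 0.13, adjusted p = 0.251). Over 18 alternative settings its log2 fold change ranged from 0.06 to 0.74 and its adjusted p from 0.0007 to 0.70.

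**Figure D1:**
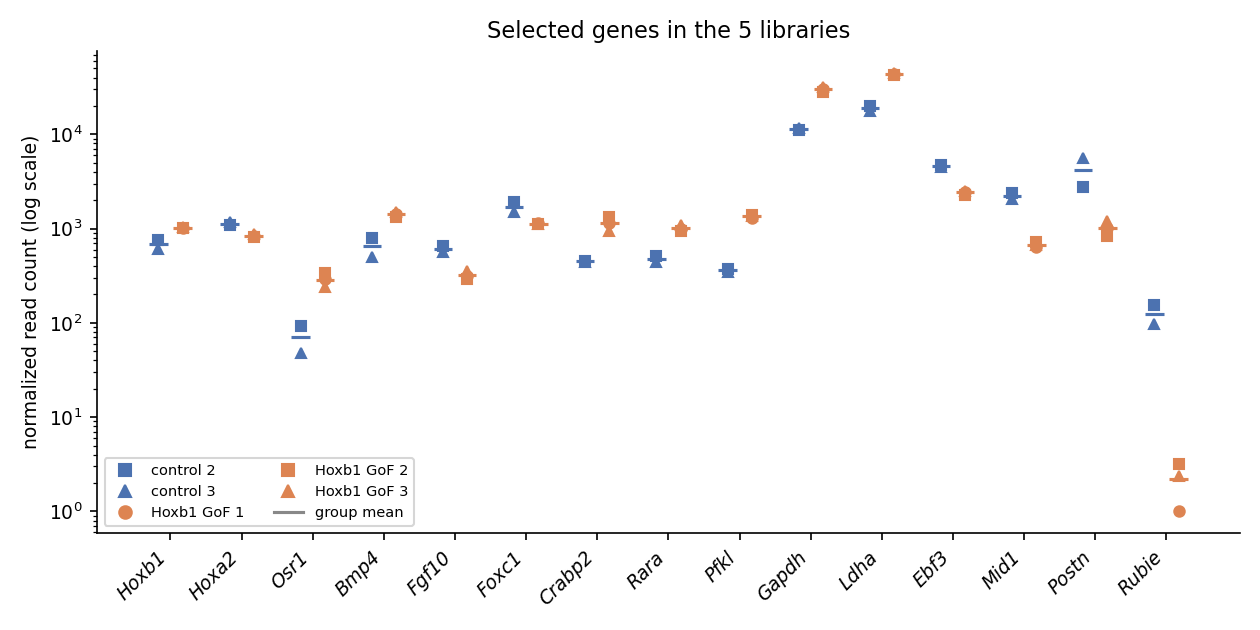
Normalized read counts (log scale) of 15 named genes in control replicates 2 and 3 (blue) and GoF replicates 1, 2 and 3 (orange), with symbols for the replicate number and a line at each group mean. For each gene shown, all values of one group lay above all values of the other, and Rubie had 153.6 and 97.3 counts in the controls against 1.0 to 3.2 in the GoF libraries.

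In all, 2054 genes were higher and 1835 lower in GoF among 16794 tested. These numbers followed the base composition of the transcripts. The log2 fold change of a gene correlated across 16266 genes with the GC content of its longest transcript (Spearman rho = 0.56, Pearson r = 0.50; genes are not independent replicates, and no p was computed). With the genes in 10 bins of about equal size by GC content, in the lowest bin, up to 40.2%, the median log2 fold change was -0.43, with 545 genes called lower and 2 higher. In the highest bin, from 56.9%, it was 0.65, with 650 genes called higher and 2 lower. The same correlation was -0.17 between control replicates 2 and 3 and 0.16 between GoF replicates 2 and 3. With the GC trend removed from each library, 507 genes were higher and 542 lower, and 735 of the 3786 original calls with a known GC content (19.4%) passed again in the same direction. Without GoF replicate 1 the counts were 678 and 554, without GoF replicate 2 they were 923 and 800, and without GoF replicate 3 they were 1362 and 1194. With GoF replicate 1 left out and the GC trend removed, 52 genes were higher and 66 lower. Each count of members and each list test given for a gene group was therefore also taken with the GC trend removed, an alternative chosen after the data were seen.

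**Figure D2:**
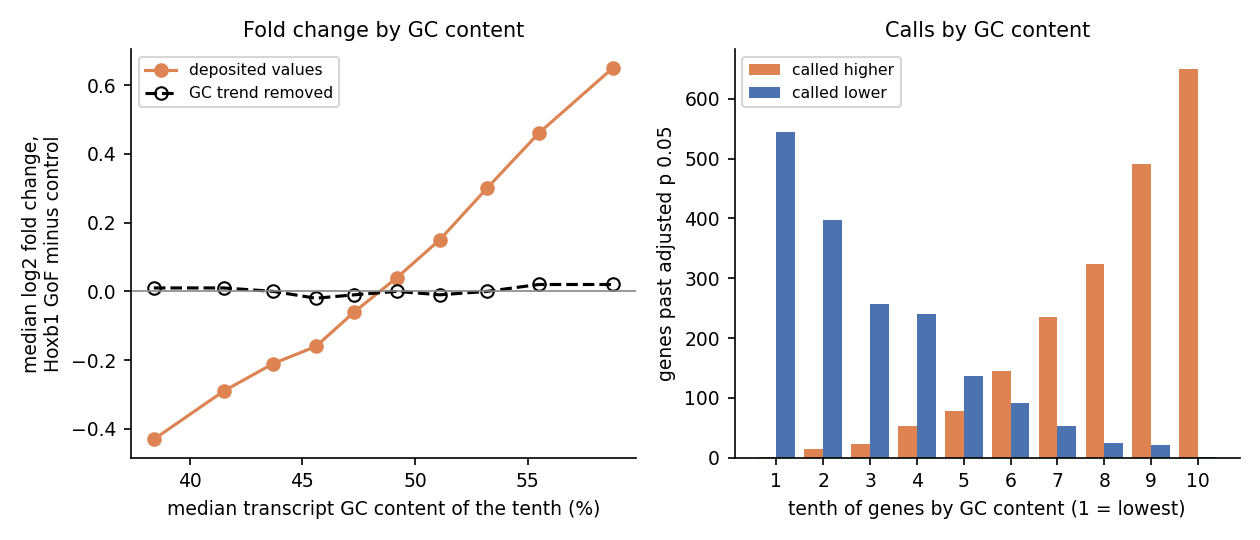
Left, median log2 fold change (GoF minus control) in 10 bins of the tested genes by transcript GC content in percent, for the deposited values (filled) and with the GC trend removed (open). Right, genes past an adjusted p of 0.05 in each bin, higher in orange and lower in blue: calls higher went from 2 in the lowest bin to 650 in the highest, and calls lower from 545 to 2.

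GoF replicate 1 lay close to the mean of the other GoF libraries. Across 9082 genes with a mean of at least 200 normalized counts, the SD of its log2 values about that mean was 0.28 times the SD of the difference between replicates 2 and 3, where 0.87 is expected of exchangeable libraries. Of 82 such genes that differed over 2-fold between GoF replicates 2 and 3, all 82 had replicate 1 between them, which choosing genes by that gap favours in any case. Its median position was 0.51 on a scale from 0 at replicate 3 to 1 at replicate 2. Among these genes were Egln3, with 383.4, 950.5 and 1630.2 counts in GoF replicates 2, 1 and 3, and Bhlhe40, with 106.0, 497.3 and 851.9, chosen as examples after their values were seen. The spread within the GoF group therefore rests mostly on replicates 2 and 3. Each SD with n = 3 and each p-value from all libraries counts replicate 1 as a separate sample. If it is not independent, these SDs and p-values tend to be too small.

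**Figure D3:**
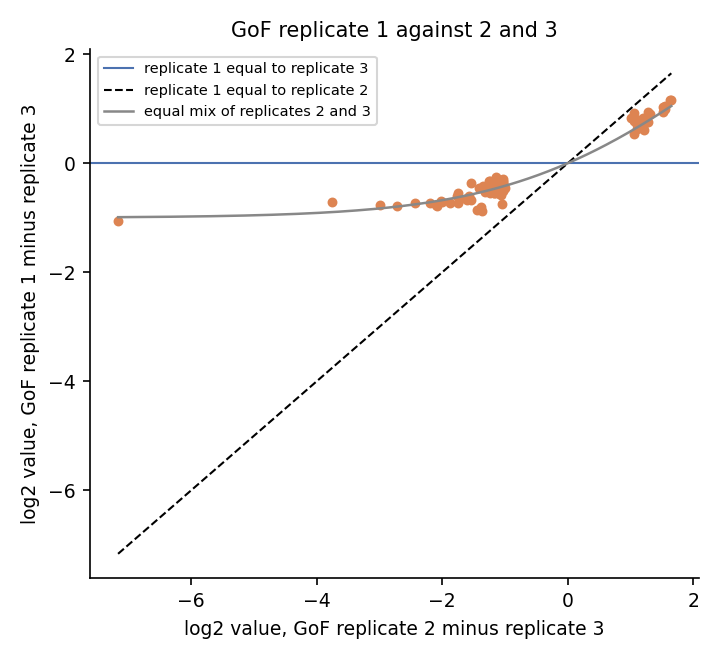
Log2 value of GoF replicate 1 minus replicate 3 (vertical axis) against that of replicate 2 minus replicate 3 (horizontal axis) for the 82 genes that differed over 2-fold between replicates 2 and 3, 1 point per gene. All points lie between the lines of equality with replicate 3 (blue) and with replicate 2 (dashed), close to the curve of an equal mix of both (grey).

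A rule fixed before the data were examined, which mostly picks genes already called, named 129 genes. By that choice, and not as a test of them, 109 passed the threshold. GC trend removal needs a GC value, which 106 of the 109 had. Of these, 34 passed also in each of 6 separate settings, without each of the 5 libraries and with the GC trend removed, and 14 of the 109 passed with the GC trend removed and GoF replicate 1 left out at the same time. The 34 included Gapdh, Pfkl, Ldha, Aldoa, Crabp1, Crabp2, Osr1, Bmp4, Id2, Cxcr4, Tnni1 and Bmf among the genes that rose. Those that fell included Fgf10, Foxc1, Ebf3, Erg, Trdn, Hrc, Mki67, Lum, Vcan, Col3a1, Cdh7 and Mid1. The lowest fold among the named genes past the threshold was that of Rubie, a long noncoding RNA (chromosome 14, 46568263 to 46598425), with 153.6 and 97.3 counts in the controls and 1.0, 3.2 and 2.4 in GoF (log2 fold change -5.32, SE 0.69, adjusted p = 0.00479; -5.28 with the GC trend removed). Bmp4 lies on the same chromosome at 46383520 to 46390669. Mid1, a ubiquitin ligase gene of the X chromosome (169685199 to 170005736), fell from 2375.5 and 2080.2 counts to 672.9 ± 40.7 (SD, n = 3; adjusted p = 0.000642). Cdh7, a cadherin, fell from 255.6 and 263.3 counts to 58.7 ± 2.5 (SD, n = 3). Abcc2, Pi15 and Grin2b were also among the 10 genes that the naming rule took for the lowest folds, at log2 fold changes of -2.09, -1.94 and -1.77. Postn, which encodes the matrix protein periostin, fell from 2776.5 and 5544.3 counts to 1021.5 ± 181.7 (SD, n = 3), and this call was lost without GoF replicate 1 (adjusted p = 0.0953).

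Among the 10 genes that the naming rule took for the highest folds were 2 features of multicopy sequence families. They were Rbpsuh-rs3, a related sequence of the Notch pathway gene Rbpj (log2 fold change 4.06), and Rn18s-rs5, an 18S ribosomal RNA copy (2.51). Reads shared between copies were not resolved here, which leaves both values uncertain. Fggy, a carbohydrate kinase gene, rose from 35.2 and 15.0 counts to 134.5 ± 10.9 (SD, n = 3; log2 fold change 2.49, adjusted p = 0.00615). Epo, which encodes erythropoietin, rose from 22.3 and 8.7 counts to 76.4 ± 17.6 (SD, n = 3; log2 fold change 2.34, adjusted p = 0.0118, and 0.0679 with the GC trend removed). The fold changes are on the scale of log2(normalized count + 1), which understates the change of genes near the floor.

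Next, 32 gene lists fixed before the data were examined were tested. Of 19 measured genes of hypoxia and glycolysis, 11 rose and 8 did not pass (15 rose when adjusted over the list alone). The median log2 fold change was 1.01, and the list stood above other genes (camera adjusted p = 4.8e-08), but not with an estimated correlation (adjusted p = 0.66). Pfkl rose from 371.7 and 349.4 counts to 1347.7 ± 52.1 (SD, n = 3), Gapdh from 11237.2 and 11589.0 to 29904.6 ± 1937.0, and Ldha from 20073.1 and 17667.5 to 43537.9 ± 1383.5. With the GC trend removed, the median was 0.71, 6 members were called higher, and the camera adjusted p was 4.7e-08. Within the GoF group 18 of the 19 members were higher in replicate 3 than in replicate 2, with a median log2 difference of 0.76. Medians relative to the control mean were 0.61, 1.02 and 1.26 for GoF replicates 2, 1 and 3. With GoF replicate 2 left out, 15 members were called higher, and with GoF replicate 3 left out, 8 were. Without GoF replicate 1 the list had 7 members called higher (camera adjusted p = 4.9e-11), as it had without control replicate 2, and over all 20 alternatives its camera adjusted p ranged from 3.7e-17 to 0.82.

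The genes encoded in the mitochondrial genome went the other way: 8 of 10 fell and 2 did not pass (9 fell when adjusted over the list alone; median log2 fold change -1.11, camera adjusted p = 9.9e-06, and adjusted p = 0.66 with an estimated correlation). The ribosomal RNAs mt-Rnr2 and mt-Rnr1 fell, with log2 fold changes of -0.77 and -0.76, although quantile normalization, which gives the most abundant feature of each library the same value, put mt-Rnr2 at 0.0 and the list at a camera adjusted p of 0.062. The messages mt-Nd4 and mt-Nd6, for subunits of complex I, fell as well (-1.44 and -1.42), calls lost without GoF replicate 1 (adjusted p = 0.161 and 0.173). The median GC content of these genes was 35.8%, and with the GC trend removed the median was -0.68, the 10 members did not pass (limma; 5 at an unadjusted p under 0.05; adjusted p = 0.202, 0.283, 0.0821 and 0.115 for mt-Rnr1, mt-Rnr2, mt-Nd4 and mt-Nd6) and the camera adjusted p was 0.002. Without GoF replicate 1, 2 members were called lower (camera adjusted p = 7.9e-09), and over 20 alternatives the camera adjusted p ranged from 3.3e-18 to 0.84. All 10 members were higher in control replicate 2 than in control replicate 3, with a median log2 difference of 0.84. Of 23 nuclear genes of oxidative phosphorylation, 7 rose and 16 did not pass (8 rose and 1 fell when adjusted over the list alone). Cox4i1, a subunit of complex IV, rose 2.41-fold and Atp5b, the beta subunit of ATP synthase, 1.40-fold. The list did not pass (camera adjusted p = 0.08), but did with the GC trend removed (0.023; adjusted p = 0.84 with an estimated correlation; range 0.0024 to 0.84 over 20 alternatives). Of its members, 4 rose without GoF replicate 1, and 3 rose and 1 fell with the GC trend removed.

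**Figure D4:**
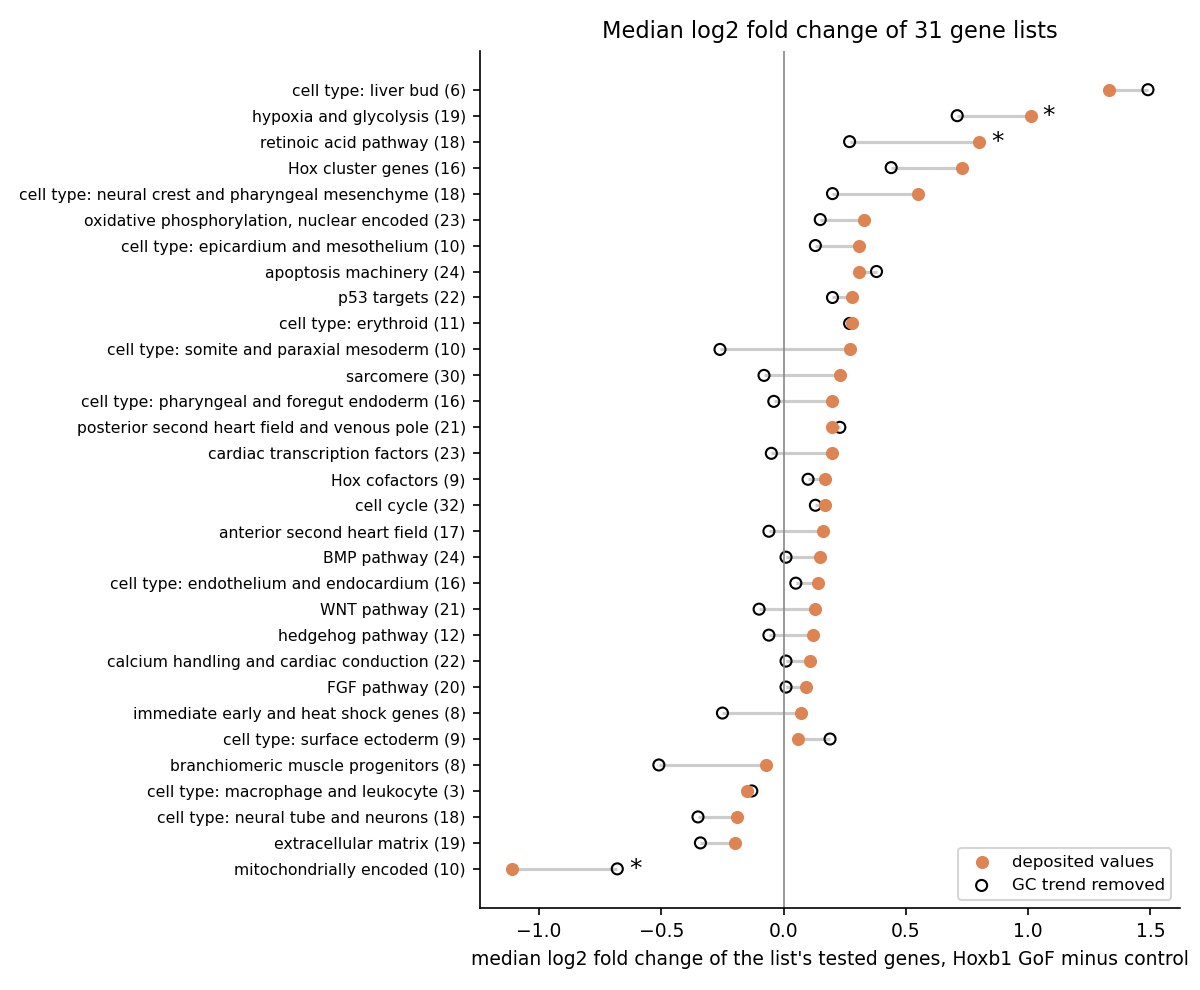
Median log2 fold change (GoF minus control) of the tested members of each gene list except the sex-linked genes, with the number of tested members in brackets, for the deposited values (filled) and with the GC trend removed (open). Stars mark the 3 lists with a camera adjusted p under 0.05 in the deposited values: hypoxia and glycolysis at 1.01, retinoic acid pathway at 0.80 and mitochondrially encoded genes at -1.11.

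In the retinoic acid pathway, 8 of 18 measured genes rose and 10 did not pass (8 when adjusted over the list alone; median log2 fold change 0.80, camera adjusted p = 0.020, and adjusted p = 0.66 with an estimated correlation). Crabp2 rose from 457.3 and 441.7 counts to 1149.5 ± 191.7 (SD, n = 3), Crabp1, a second cellular retinoic acid binding protein gene, rose 2.21-fold, Rara, a retinoic acid receptor, 2.11-fold and Stra6, a retinol transporter, 2.55-fold. With the GC trend removed the median was 0.27, 2 members, Crabp1 and Crabp2, stayed past the threshold, and the list did not (camera adjusted p = 0.19). When GoF replicate 1, 2 or 3 was left out, 4 members rose in each case. Of the 18 members of the list, 13 were higher in control replicate 2 than in control replicate 3, with a median log2 difference of 0.27. Over its 20 alternatives the camera adjusted p ranged from 0.0012 to 0.87. Aldh1a2, which makes retinoic acid in the posterior second heart field, had 2484.5 and 169.7 counts in the controls and 2527.6, 2711.2 and 2389.9 in the GoF libraries, and did not pass (adjusted p = 0.379).

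Of 21 posterior second heart field and venous pole genes, 5 rose and 16 did not pass, with the same count when adjusted over the list alone. Hoxb1 itself, whose rise the GoF design intends, is among the 5. Osr1 rose from 92.6 and 47.4 counts to 288.3 ± 47.8 (SD, n = 3; adjusted p = 0.00572, and 0.0348 with the GC trend removed) and Bmp4 from 797.3 and 499.2 to 1419.5 ± 78.7 (adjusted p = 0.00726, and 0.0404). Gli1, a target and effector of hedgehog signalling, rose 1.91-fold, a call lost without GoF replicate 1 (adjusted p = 0.0509) and with the GC trend removed (0.326). The list did not pass (median 0.20, camera adjusted p = 0.08), nor did it with Hoxb1 left out of it. After GC trend removal 2 members were higher, Osr1 and Bmp4, and 1 was lower, Nr2f1, a nuclear receptor gene named after its value was seen (camera adjusted p = 0.21). The list passed without GoF replicate 1 (2 members higher, camera adjusted p = 0.041), and with an estimated correlation on all libraries it did not (adjusted p = 0.66). Of its 21 members, 17 were higher in control replicate 2 than in control replicate 3, with a median log2 difference of 0.47. Without control replicate 2, 12 members were higher, and without control replicate 3, 4 were higher and 5 lower. Its camera adjusted p ranged from 1.8e-05 to 0.95 over 21 alternatives. Of 16 Hox cluster genes, Hoxb1 rose, Hoxa2 fell and 14 did not pass. Hoxa2 went from 1082.2 and 1169.3 counts to 840.5 ± 31.7 (SD, n = 3; adjusted p = 0.0255), a call lost without GoF replicate 1 (0.136) or 2 (0.079). The list did not pass (median log2 fold change 0.73, camera adjusted p = 0.23), and without control replicate 2, 9 members were higher and 1 lower. After GC trend removal Hoxa2 was lower and the other 15 did not pass (camera adjusted p = 0.8; range 0.0003 to 0.91 over 21 alternatives). Hox genes of paralog groups 4 to 7 differed within the controls, so that Hoxb4 had 302.5 and 49.9 counts there against 265.9 ± 7.9 in GoF, and Hoxa5 198.2 and 22.5 against 124.6 ± 2.8. Among 9 Hox cofactors, Meis3 rose 2.07-fold, Pknox2 fell to 0.74 of the control level and 7 did not pass (camera adjusted p = 0.49). The Pknox2 call was lost without GoF replicate 1 (adjusted p = 0.069) or 2 (0.056), and the Meis3 call with the GC trend removed (0.12), where 1 cofactor was higher and 1, Pknox2, lower. Without control replicate 3, 2 cofactors were higher and 3 lower, and without control replicate 2, 2 were higher and 1 lower.

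In the anterior second heart field list, 3 of 17 genes rose, 3 fell and 11 did not pass (4 and 4 when adjusted over the list alone; camera adjusted p = 0.66). These counts were 1 and 3 without GoF replicate 1 or 3, 2 and 3 without GoF replicate 2, and 5 and 3 without control replicate 3. They were 2 and 2 with the GC trend removed. Fgf10 fell from 653.1 and 557.8 counts to 320.5 ± 34.3 (SD, n = 3) and Foxc1, a forkhead factor of the pharyngeal mesoderm, from 1926.4 and 1487.5 to 1129.1 ± 8.8. Cxcr4, a chemokine receptor gene, rose 2.61-fold. Sema3c, a guidance molecule of the outflow tract, fell to 0.57 of the control level, a call lost with the GC trend removed (adjusted p = 0.0868). Of 8 branchiomeric muscle progenitor genes, 2 fell, Ebf3 and Ebf2, and 6 did not pass (3 fell when adjusted over the list alone; camera adjusted p = 0.35; range 0.033 to 0.66 over 20 alternatives). Ebf3 was the 1 member called after GC trend removal. Ebf3 went from 4775.6 and 4537.3 counts to 2420.6 ± 130.4 (SD, n = 3), and the Ebf2 call was lost without GoF replicate 1 (adjusted p = 0.09) or 2 (0.053).

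Heart muscle genes moved both ways. Of 30 sarcomere genes, 6 rose, 5 fell and 19 did not pass, with the same counts when adjusted over the list alone (median log2 fold change 0.23, camera adjusted p = 0.40). Myl7, the atrial myosin light chain, rose 1.68-fold and Tnni1, slow skeletal troponin I, 2.33-fold, while Nebl, which encodes nebulette, fell to 0.65 of the control level. With the GC trend removed, 1 sarcomere gene was called higher and 7 lower (median -0.08, camera adjusted p = 0.18; range 0.026 to 0.93 over 20 alternatives). Of its members, 2 rose and 3 fell without GoF replicate 1, and without GoF replicate 2, 3 rose and 3 fell, and without control replicate 3, 12 rose and 4 fell. Tnni1 stayed past the threshold (adjusted p = 0.0115), and Myl7 (0.082) and Nebl (0.0539) did not. Of 22 genes of calcium handling and conduction, 2 rose, 4 fell and 16 did not pass, with the same counts when adjusted over the list alone (camera adjusted p = 0.85). These counts were 6 and 5 without control replicate 2, and 2 and 2 without GoF replicate 1 or 2. They were 1 and 3 with the GC trend removed. Trdn, which encodes triadin of the calcium release complex, fell from 1045.9 and 692.6 counts to 345.2 ± 32.4 (SD, n = 3), and Hrc, a calcium-binding protein gene of the sarcoplasmic reticulum, from 1492.6 and 1488.7 to 976.9 ± 54.3. Hcn4, the pacemaker channel gene, rose 2.11-fold and Kcnh2, a potassium channel gene, 2.42-fold, calls lost with the GC trend removed (adjusted p = 0.126 and 0.176). Of 23 cardiac transcription factors, 6 rose, 1, Mef2a, fell and 16 did not pass (7 rose when adjusted over the list alone; median 0.20, camera adjusted p = 0.20). After GC trend removal the 7 called factors did not pass, and 2 others, Irx3 and Irx5, homeobox genes named after their values were seen, were lower. When GoF replicate 1 was left out, 1 rose and 1 fell, and without GoF replicate 2 or 3, 2 rose and 1 fell. Mef2d rose 1.54-fold, and Mef2a fell to 0.67 of the control level, calls lost with the GC trend removed (adjusted p = 0.267 and 0.0636).

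Of 22 p53 targets, 5 rose and 17 did not pass, with the same count when adjusted over the list alone. Cdkn1a, a cell cycle inhibitor, rose from 85.6 and 48.7 counts to 190.3 ± 9.3 (SD, n = 3; adjusted p = 0.00935, and 0.053 with the GC trend removed), and Ei24, an autophagy gene, 1.77-fold. Of 24 genes of the apoptosis machinery, 7 rose, 1 fell and 16 did not pass, with the same counts when adjusted over the list alone. Bmf, a pro-apoptotic BH3 protein gene, rose 2.13-fold, and Bak1, a pro-apoptotic pore protein gene, 1.88-fold, the second call lost with the GC trend removed (adjusted p = 0.22). Neither list passed (camera adjusted p = 0.097 and 0.08), and both did with the GC trend removed (0.015 and 0.022; adjusted p = 0.4 for each with an estimated correlation). In that fit, 2 p53 targets and 1 apoptosis gene were called higher. Over 20 alternatives the p53 list ranged from 0.0072 to 0.66 and the apoptosis list from 0.018 to 0.66. When GoF replicate 1 was left out, 2 p53 targets rose, and 3 apoptosis genes rose and 1 fell, and without GoF replicate 2, 3 p53 targets and 3 apoptosis genes rose. Of 32 cell cycle genes, 7 rose, 2 fell and 23 did not pass (8 and 3 when adjusted over the list alone; camera adjusted p = 0.28; range 0.029 to 0.89 over 20 alternatives). When GoF replicate 1 or 2 was left out, 2 rose and 1 fell, and without control replicate 3, 8 rose and 6 fell. The 7 genes that rose did not pass after GC trend removal, and 2 genes fell. Mki67 fell from 86478.5 and 72438.1 counts to 49321.8 ± 697.6 (SD, n = 3), whereas Mcm2, a replication helicase subunit, rose 1.53-fold and Aurkb, a mitotic kinase, 1.49-fold, calls lost with the GC trend removed (adjusted p = 0.0522 and 0.0573).

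Genes of the extracellular matrix fell more often than they rose: 6 of 19 fell, 2 rose and 11 did not pass, with the same counts when adjusted over the list alone. Lum, which encodes the proteoglycan lumican, fell to 0.49 of the control level, Vcan, versican, to 0.68, and Col3a1, a fibrillar collagen chain, to 0.65. The list did not pass (median log2 fold change -0.20, camera adjusted p = 0.08). With the GC trend removed, 10 members fell (median -0.34, camera adjusted p = 0.00046, and adjusted p = 0.4 with an estimated correlation). Of its members, 3 fell without GoF replicate 1 (camera adjusted p = 0.041), and without control replicate 3, 9 fell and 2 rose. Its camera adjusted p ranged from 2.2e-05 to 0.66 over 20 alternatives.

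The lists of the other signalling pathways did not pass. The BMP pathway had 3 of 24 members higher and 3 lower (4 and 3 when adjusted over the list alone; camera adjusted p = 0.44). The FGF pathway had 3 of 20 higher and 3 lower, with the same counts when adjusted over the list alone (0.43), and the hedgehog pathway 2 of 12 higher and 10 not passed (2 when adjusted over the list alone; 0.29). The WNT pathway had 2 of 21 higher and 2 lower (0.4), and adjusted over the list alone its 21 members did not pass (limma; 6 at an unadjusted p under 0.05, and 5 called by DESeq2 and 1 by edgeR over all genes). After GC trend removal the 2 hedgehog calls, Gli1 and Gli2, did not pass and 2 other members were lower, Smo, the hedgehog signal transducer, and Gas1, a hedgehog coreceptor gene, both named after their values were seen. In the same fit 2 BMP genes were higher and 1 lower, 1 FGF gene, Fgf10, was lower, and the 21 WNT genes did not pass (limma; 4 at an unadjusted p under 0.05). The 2 hedgehog calls were also lost without GoF replicate 1 (adjusted p = 0.0509 for Gli1 and 0.073 for Gli2), whereas 5 members were higher without control replicate 2, and 4 higher and 2 lower without control replicate 3. The WNT calls, Sfrp5, Axin2, Lef1 and Wnt5a, were each lost in 4 of the 5 settings without 1 library, and the list had no call without GoF replicate 1 or 2 (limma; 3 and 5 members at an unadjusted p under 0.05) and 1 lower without GoF replicate 3. When GoF replicate 1 was left out, 2 BMP genes rose and 2 fell, and 1 FGF gene rose and 1 fell. Without GoF replicate 2 the counts were 2 and 1 for BMP and 1 and 2 for FGF, and without GoF replicate 3 they were 3 and 2, and 1 and 3, while without control replicate 3 the counts were 6 and 5 for BMP and 5 and 3 for FGF. Among these genes Id2, a BMP target, rose 1.69-fold, Bmpr2, a BMP receptor, fell to 0.62 of the control level, and Spry4, an antagonist of receptor tyrosine kinase signalling, rose 2.04-fold (adjusted p = 0.0584 with the GC trend removed). The immediate early and heat shock genes had no member past the threshold among 8 (limma; 0 at an unadjusted p under 0.05, and 0 with edgeR and DESeq2; camera adjusted p = 0.6).

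Lists of cell types that a dissected region could hold were tested in the same family and did not pass. Adjusted over the list alone, the counts were 5 and 1 for neural crest, 6 and 1 for endoderm and 6 and 3 for endothelium, and those of the other cell types did not change. Neural crest and pharyngeal mesenchyme had 4 of 18 members higher and 1 lower (camera adjusted p = 0.097), pharyngeal endoderm 4 of 16 and 1 (0.25), and endothelium 4 of 16 and 3 (0.28). Without GoF replicate 1, 2 endoderm genes rose, and 1 endothelial gene rose and 1 fell. Without GoF replicate 2, 2 endoderm genes and 2 endothelial genes rose and 1 endothelial gene fell, and without GoF replicate 3, 2 endothelial genes rose and 2 fell. After GC trend removal, 1 endoderm gene and 1 endothelial gene, Erg, were called, both lower, and 1 neural crest gene was higher and 1 lower. Erythroid genes had 3 of 11 higher and 8 not passed (0.28). Of these 3 calls 1 passed without GoF replicate 1, and they did not pass without GoF replicate 3 (limma; 3 members at an unadjusted p under 0.05) or after GC trend removal, where 1 member was lower. The other lists had fewer calls: epicardium 1 of 10 higher and 1 lower (0.44), paraxial mesoderm 1 of 10 and 1 (0.85) and surface ectoderm 1 of 9 higher (0.43). After GC trend removal 2 paraxial mesoderm genes were lower, and the called genes of epicardium, surface ectoderm and liver bud did not pass (limma; 1, 2 and 1 members at an unadjusted p under 0.05). Without control replicate 2, 5 paraxial mesoderm genes were higher and 1 lower, and 3 epicardium genes and 2 surface ectoderm genes were higher. Without control replicate 3, the counts were 2 and 2 for paraxial mesoderm and epicardium, and 3 and 1 for surface ectoderm. In the settings without 1 GoF library, 1 epicardium gene was higher and the surface ectoderm genes did not pass (limma; 1 at an unadjusted p under 0.05 in each case). Of the paraxial mesoderm genes, 1 was lower without GoF replicate 1 or 3, and they did not pass without GoF replicate 2 (limma; 2 at an unadjusted p under 0.05). Of 6 liver bud genes, Prox1 fell and 5 did not pass (0.66; range 0.00037 to 0.91 over 20 alternatives), and the Prox1 call was lost without GoF replicate 1 (adjusted p = 0.123), GoF replicate 2 (0.088) or control replicate 2 (0.07). Without control replicate 2, 5 liver bud genes were higher and that list passed (camera adjusted p = 0.0020), and without control replicate 3, 3 were lower. Without control replicate 3, 10 neural crest genes were higher and 1 lower, and that list passed (camera adjusted p = 0.010, and 0.0079 with the GC trend also removed; range 0.0079 to 0.89 over 20 alternatives). Of this list, 1 member was higher without GoF replicate 1, and 1 was higher and 1 lower without GoF replicate 2 or 3. Cdh5, an endothelial cadherin, rose 1.53-fold (adjusted p = 0.0737 with the GC trend removed) and Erg, an endothelial transcription factor, fell to 0.48 of the control level. Krt18, a keratin of simple epithelia, rose 2.08-fold (adjusted p = 0.0893 with the GC trend removed). Of 18 neural genes, 1 rose, 3 fell and 14 did not pass (0.25), and the list passed with the GC trend removed (0.015; adjusted p = 0.4 with an estimated correlation; range 0.01 to 0.66 over 20 alternatives). In that fit the 4 called members did not pass (adjusted p = 0.0607 for Elavl4, 0.0546 for Pou3f2, 0.0889 for Neurod1 and 0.126 for Tubb3) and 2 others were lower. In the deposited values 2 neural genes were lower without GoF replicate 1 or 2, and 3 without GoF replicate 3. Elavl4, a neuronal RNA-binding protein gene, fell to 0.45 of the control level (adjusted p = 0.00686). The 3 macrophage genes measured had none past the threshold (limma; 0 at an unadjusted p under 0.05, and 0 with edgeR and DESeq2; camera adjusted p = 0.85).

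The authors' deposited table lists 2211 genes higher and 2241 lower at an adjusted p under 0.05, and 667 and 424 of them with an absolute log2 fold change of at least 1. In the authors' deposited table Hoxb1 has a log2 fold change of 0.59 and an adjusted p of 0.000702. Of the 3889 calls made here, the authors' deposited table calls 3807 in the same direction (97.9%). Both comparisons rest on the same libraries and the same factors, so this overlap is not independent evidence for the calls.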

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

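The GC trend removal, its combinations and the edgeR test were chosen after the result was seen, and the other alternatives before. The design has 2 control libraries, and where a setting leaves 1 of them, that library is assumed to vary like the others. Leaving out control replicate 1 was not run, as it was not analysed here. The deposited table holds no gene under a mean normalized count of 6.1, and whether depth or a filter set this was not tested. For each value below that changed, the cause was not tested.

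With quantile normalization, no filter, a mean of at least 50, array weights, pseudocounts of 0.5 or 5, DESeq2 or edgeR, the counts of genes higher (2054) and lower (1835) stayed within 1.5 times, and Hoxb1 stayed past the threshold. Without each library in turn the counts were 678 to 2734 higher and 554 to 2552 lower, and the Hoxb1 log2 fold change was 0.44 to 0.74, with the call lost without GoF replicate 1 (0.59). A block for the replicate number, which the labels do not say pairs the samples, gave 765 higher and 606 lower, and Hoxb1 at 0.59 (adjusted p = 0.062). Limited to an absolute log2 fold change of at least 1, 649 were higher and 315 lower, and 1091 of the authors' deposited calls met that limit, fewer by construction.

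With the GC trend removed, 507 genes were higher and 542 lower, and Hoxb1 did not pass (0.26). Without GoF replicate 1 as well, the counts were 52 and 66 and Hoxb1 did not pass (0.27). Without control replicate 2 as well, they were 1361 and 1060 and Hoxb1 passed (0.46, adjusted p = 0.034). Without control replicate 3 as well, they were 960 and 945, and Hoxb1 did not pass (0.061). In that order of the 4 settings, Srf reversed to -0.26, -0.26, -0.26 and -0.27, and Gli2 to -0.046, -0.054, -0.094 and -0.003. Dnajb1 reversed to -0.44 without control replicate 2. Without control replicate 3, Bmp7 reversed to -0.12, Axin2 to -0.14, Meox1 to -0.011, Hoxa5 to -0.76, Hoxb4 to -0.67 and Hoxd4 to -1.41 (-1.405). In the deposited values Hoxa5 went from -0.67 to 2.42 without each library in turn. With the trend removed from all libraries, 66 named genes lost their call in the same direction.

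The list of the retinoic acid pathway lost its call with the GC trend removed from all libraries (camera adjusted p = 0.19), and with it removed and without GoF replicate 1 (0.12) or control replicate 3 (0.87), but not with it removed and without control replicate 2 (0.014). It passed in the deposited values without each library in turn, and lost its call with edgeR (0.053), and with an estimated correlation (0.66, and 0.84 with the GC trend removed). Hypoxia and glycolysis lost it with an estimated correlation alone (0.66, and 0.82 with the GC trend removed). The mitochondrially encoded genes lost it with quantile normalization (0.062), with the GC trend removed and without control replicate 2 (0.11), and with an estimated correlation (0.66, and 0.84 with the GC trend removed). Lists that passed in the opposite direction were Hox cluster genes (0.0079), liver bud (0.038) and somite (0.015) with the GC trend removed and without control replicate 3, and sarcomere (0.026) with it removed and without control replicate 2. The sex-linked list passed in the opposite direction without control replicate 2 (0.035), in a range of 0.033 to 0.74 without each library in turn.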

Other observations

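The test on the GC trend was written before its result was seen, and the other tests of this part were chosen after the result was seen, as were the genes named in it. Genes of the response to low oxygen differed within the GoF group. Bhlhe40, a transcriptional repressor, had 106.0 counts in GoF replicate 2 and 851.9 in replicate 3. Ddit4, an mTOR inhibitor gene, had 59.9 and 454.7, and Egln3, an oxygen-sensing hydroxylase gene, 383.4 and 1630.2. Control replicates 2 and 3 had 172.4 and 59.9 counts of Bhlhe40, 32.8 and 58.7 of Ddit4, and 317.7 and 205.9 of Egln3. Between the groups these genes did not pass (limma adjusted p = 0.249, 0.105 and 0.0959). Inside Mid1 on the X chromosome, on the opposite strand, lie G530011O06Rik (741.0 and 507.9 counts in the controls, 19.5, 46.1 and 23.5 in GoF) and Gm15726 (231.0 and 119.8, against 14.4, 23.5 and 22.7), so these falls are not shown to be separate from that of Mid1. Gm7809 had 1240.5 and 1198.0 counts in the controls and 134.3, 133.5 and 125.4 in GoF, and Gm21451 had 1.2 and 1.2 against 114.8, 79.3 and 135.1. Zfp990, a zinc finger gene, had 4.0 counts in GoF replicate 2 and 723.3 in replicate 3. Xist, the X inactivation RNA of female cells, had 186495.8 counts in control replicate 2, 394.3 in control replicate 3 and 191.8, 181.2 and 213.6 in GoF, and the Y-linked Kdm5d had 9.4, 3304.4, 2770.6, 2653.0 and 3079.2. Going by these genes, control replicate 2 was female, and control replicate 3 and the GoF libraries were male. Sex was thus not matched between the groups. The 6 sex-linked genes did not pass between the groups (limma; 1 at an unadjusted p under 0.05, 1 with DESeq2, 0 with edgeR; camera adjusted p = 0.67). This does not show matched groups, as the controls had opposite values (Xist log2 fold change -5.45, SE 3.21).

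Fold changes followed transcript GC content (Spearman rho = 0.56), and with the trend removed 19.4% of the calls passed again in the same direction and 312 other genes were called, so a composition bias of amplification or library preparation may underlie many calls. The 735 calls that passed again kept a median of 92.1% of their log2 fold change (quartiles 71.9 and 112.4), and 90.8% when GoF replicate 1 was also left out. Their choice by passing with the trend removed favours a high share, so the shares themselves cannot exclude the removed trend as the whole cause. A change owed to that trend alone would be gone after its removal. Yet 1049 genes passed in that fit, against 8 unchanged genes in the simulation with its trend removed. For these calls as a set, this argues against the removed trend as the whole cause. The simulated libraries were independent, so the margin need not hold if GoF replicate 1 is not. With GoF replicate 1 also left out, 107 of the 3786 calls with a known GC content (2.8%) passed again. The other 3051 calls, that of Hoxb1 among them, kept a median of 46.6%. For them the removed trend as the whole cause stays open, since a missed threshold does not show that nothing changed. Leaving out GoF replicate 1 alone took the calls from 3889 to 1232 while a median of 99.5% of the log2 fold change was kept. The genotype raising GC-rich transcripts cannot be told apart from a bias, since preparation batches are not given, and the largest correlation within a group was 0.17 in size.

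Across 9082 genes the SD of GoF replicate 1 about the mean of GoF replicates 2 and 3 was 0.28 times the SD of their difference, where 0.87 is expected of exchangeable libraries, which argues against an independent sample. Merged and subsampled reads of both are argued against by a variance ratio of 1.31, as a simulated subsample gave 0.44. The simulated value came from a single draw and shares of total reads, and the observed value from normalized counts. Both therefore compare only roughly. An equal mix of the material behind replicates 2 and 3, with its own library, may explain the pattern (variance ratio 1.31 about the mix, against 12.5 between replicates 2 and 3). No biological explanation was tested, and if it is a mix the GoF group holds 2 independent samples.

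In the controls, 14 of 14 liver bud genes and Hox genes of paralog groups 4 to 7 (100.0%) were higher in replicate 2, with a median log2 difference of 3.33, against 50.7% of all tested genes. Apob had 7112.4 and 169.7 counts, Afp 419.8 and 8.7, Aldh1a2 2484.5 and 169.7, and Shox2 286.1 and 10.0 in control replicates 2 and 3. A GC bias is argued against, since 102.7% of the median was kept with the trend removed. A dissection with less posterior and hepatic tissue in control replicate 3 may explain it, and a difference in stage stays open and untested. The controls also differed in the sex-linked genes, and whether that bears on the posterior genes was not tested.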
